A study of Mus musculus with 46 samples.

How the data were processed

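The deposited quantification files, made by the authors with Salmon, held estimated counts per transcript (expected counts with decimals, not normalised) and TPM. Per the submitters' processing notes, FastQC, STAR, Salmon and DESeq2 were used with build GRCm38.p4, and no versions were given. Each file held 115088 transcripts, of which 114200 were matched to GENCODE release M21 and summed to 47311 genes. The 888 unmatched transcripts carried 0.173% to 0.337% of the reads and were left out. Effective lengths were the length less 249 bases in all 46 files, so the files carry no length correction that differs between libraries. Mitochondrial transcripts had no counts, and the list of them could not be tested.

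Gene counts were rounded to whole numbers and fitted with edgeR 4.0.16 (quasi-likelihood F test, TMM scaling, prior count 0.125) in R 4.3.3 with limma 3.58.1. The fits were 1 for the BMDM, M1 and M2 libraries, 1 for DC and DCstim, 1 for iMC and 1 for tumours. Genes were kept by filterByExpr (minimum count 10, minimum total 15), leaving 17851, 17437, 16186 and 17012 genes. P-values were adjusted by Benjamini-Hochberg within each comparison, and a gene was called at adjusted p under 0.05. Different responses of the genotypes to a stimulus were tested as the difference of the 2 log2 fold changes.

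Gene lists, 42 in number, were fixed before the data were examined, and 41 could be tested with at least 5 measured members. Each was tested with camera at a preset correlation of 0.01, adjusted over the lists of a comparison, with the correlation estimated from the data as the alternative and the fry rotation test as another. Calls within a list were counted from the adjustment over all genes and from an adjustment over the list alone. The genes named are Prkcd, the 8 largest rises and falls of each genotype comparison (5 for stimulus comparisons) among genes with adjusted p under 0.05, at least 10 CPM in a group and no overlap between groups (overlap was allowed in tumours), and for each list up to 4 called members with the lowest adjusted p. Where no member passed, up to 2 with the largest fold change are given as values only, and predicted gene models were passed over. A further 6 genes that the rule names are not reported here.

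The alternatives were DESeq2 1.42.0 (Wald test), DESeq2 size factors, length-scaled counts, no filter on low counts, a fit of only the groups compared, the replicate number as a block, the number of digits of the tumour's number as a covariate, and leaving out each library once. Added after the values had been seen were the replicate number as a block within genotype, leaving out ribosomal RNA genes in tumours, and leaving out BMDM KO replicate 3 and M2 WT replicate 1 together. Other choices of scaling moved the median of all genes by less than 0.1. Groupings of the same samples other than KO and WT were also fitted, all 10 for groups of 3 against 3, 100 of 462 for tumours and 50 of 200 for differences of responses.

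Whether equal replicate numbers mark related cultures was checked from the correlation of deviations from the group mean over 11879 genes. BMDM KO and WT libraries of 1 number correlated at 0.114 to 0.178, DC KO with DCstim KO at 0.316 to 0.487, DC WT with DCstim WT at 0.136 to 0.431 and BMDM KO with M1 KO at 0.112 to 0.293, each above all pairs of unlike number or over 0.1 throughout. Of KO and WT pairs of 1 culture, BMDM alone passed this rule. The fits without a block had been fixed before the data were examined and were kept for all genotype comparisons, and BMDM had 234 calls with the block against 203.

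The steps were tested on simulated data drawn at the measured levels and spreads. A change of log2 1 was called for 76.1% of genes in the BMDM and tumour designs. A difference of log2 1 in response was called for 64.2% (DCstim) and 68.7% (M2). False calls were 5.06% of calls in BMDM and 7.56% for M1 against BMDM in WT. Over the 16 designs they ran from 3.08% (M2 difference) to 9.49% (iMC). A list shifted by 0.5 was called in all 16 comparisons, which leaves correlation between genes untested. Tables and figures were made in Python 3.11.15 with pandas 2.3.3, numpy 2.4.6, scipy 1.17.1 and matplotlib 3.10.9. Raw reads and the antibody treatment of tumours were not analysed here.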

Results

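RNA sequencing libraries from mice with and without a knockout of Prkcd, the gene of protein kinase C delta, were compared in 6 kinds of bone marrow culture and in E0771 mammary tumours. The 46 libraries comprised 3 knockout (KO) and 3 wild-type (WT) libraries each of macrophages grown in M-CSF (BMDM), macrophages given interferon gamma and LPS (M1), dendritic cells grown in FLT3L (DC), dendritic cells given LPS and an antibody to CD40 (DCstim) and immature myeloid cells grown in GM-CSF and IL-6 (iMC). Macrophages given IL-4 (M2) had 2 KO and 3 WT libraries, and tumours from mice on a high fat diet had 5 KO and 6 WT. Depth ran from 23.4 to 77.9 M estimated counts per library (mean 54.9 M). The labels do not show which cultures came from separate animals or which antibody each tumour's host received, so every p-value measures only the spread between these samples.

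Prkcd (ENSMUSG00000021948, GRCm38 chromosome 14, 30595354 to 30626210) encodes a lipid-activated kinase that needs no calcium and was still measured in every KO library, at a lower level than in every WT library of the same culture. Levels in TPM (mean ± SD, KO against WT) were 111 ± 5.58 against 143 ± 5.83 in BMDM, 134 ± 11.8 against 192 ± 3.09 in M1, 262 ± 12.1 against 408 ± 20 in M2 and 194 ± 20.9 against 256 ± 15.5 in DC. They were 172 ± 16.8 against 234 ± 6.76 in DCstim, 146 ± 14 against 169 ± 4.29 in iMC and 43 ± 9.66 against 41.6 ± 7.28 in tumours. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, the log2 fold change (± standard error, KO over WT) was −0.49 ± 0.07 in BMDM (adjusted p = 8.53e-04), −0.71 ± 0.07 in M1 (9.97e-06), −0.86 ± 0.08 in M2 (8.26e-06), −0.47 ± 0.07 in DC (0.011) and −0.58 ± 0.07 in DCstim (0.00183). In iMC the value was −0.39 ± 0.08 and did not pass (adjusted p = 0.0718), and in tumours, whose cancer cells carry their own Prkcd, it was 0.07 ± 0.09 (adjusted p = 0.846), with KO libraries at 31.9 to 57.1 TPM and WT libraries at 34.5 to 51.7.

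Prkcd transcripts parted the genotypes further than the gene sum, but overlap, so their split of reads is uncertain. ENSMUST00000112207, which begins at an internal exon (chromosome 14, 30595592 to 30607822, 15 exons), had 34.6 TPM in BMDM KO against 5.73 in WT, 37.6 against 4.11 in M1, 90.5 against 11.4 in M2, 49.2 against 7.21 in DC, 45.8 against 7.32 in DCstim and 32.0 against 2.56 in iMC. In tumours it had 4.55 against 0.958 TPM, the lowest KO (2.52) above the highest WT (2.45). The 18-exon ENSMUST00000112210, which spans the gene, fell to 0.431 of its WT level in BMDM (43.2 against 100 TPM), 0.381 in M1, 0.336 in M2, 0.430 in DC, 0.388 in DCstim and 0.490 in iMC, and was at 0.933 in tumours. These ratios were taken after the values were seen and carry no test.

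**Figure D1:**
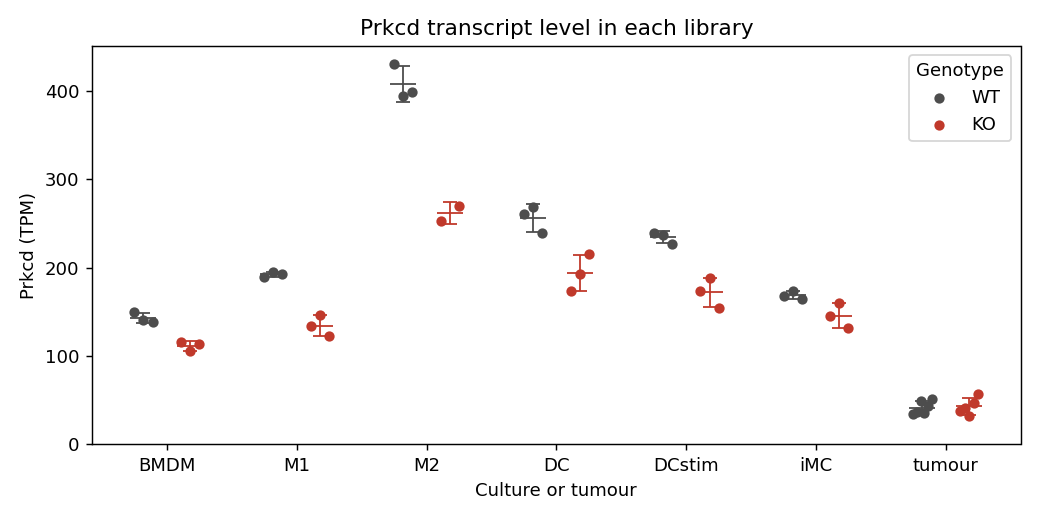
Prkcd level in TPM (vertical axis) for each library by kind of sample and genotype, with the mean and SD of each group. KO libraries of BMDM, with a mean of 111 TPM, lie under the WT libraries at 143, and the tumour groups overlap.

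In unstimulated macrophages of the knockout, 14 of 51 antiviral interferon-stimulated genes fell and 11 of 15 B-lineage markers rose (3 KO, 3 WT). Oasl2 (−1.15 ± 0.20), Rtp4 (−1.10 ± 0.23), Dhx58 (−0.77 ± 0.10) and Oas1g (−0.87 ± 0.18), which act in RNA sensing and viral restriction, fell. Ddx58 (−0.76 ± 0.11), Stat2 (−0.70 ± 0.11) and Eif2ak2 (−0.43 ± 0.07) fell with them (edgeR adjusted p from 4.20e-04 to 0.0422). Oasl2 (ENSMUSG00000029561, chromosome 5, 114896936 to 114912234) stood at 82 ± 13.1 against 182 ± 46.1 CPM. The immunoglobulin and B-cell genes Igha (2.90 ± 0.19), Jchain (2.51 ± 0.15), Ighm (2.46 ± 0.25), Iglc2 (2.34 ± 0.25) and Igkc (2.19 ± 0.35) rose. Igha (ENSMUSG00000095079, chromosome 12, 113254830 to 113260236) stood at 191 ± 19.3 against 25.6 ± 1.25 CPM. The B-cell surface and receptor genes Cd79a (2.19 ± 0.28), Ms4a1 (2.19 ± 0.25) and Fcmr (1.91 ± 0.39) rose with them (edgeR adjusted p from 5.09e-08 to 0.0289 over the 8). In all, 132 genes were higher and 71 lower of 17851 tested. Of the 132, 36 were immunoglobulin genes, whose reads are shared between near-identical segments so that single values are uncertain.

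Of the 51 members of the interferon I antiviral list, 0 rose, 14 fell and 37 did not pass, against 1 and 34 adjusted over the list alone (median −0.48, camera adjusted p = 3.84e-39, and 0.189 with an estimated correlation). Its median was −0.798 without BMDM KO replicate 3 and −0.316 without WT replicate 3. The interferon gamma response list did not move: of 48 members 1 rose, 0 fell and 47 did not pass, against 1 and 1 over the list alone (median 0.157, adjusted p = 0.877). The direction of that list hung on 1 library, since without KO replicate 3 its median was −0.271 (adjusted p = 0.00144) and without KO replicate 2 it was 0.385 (0.0165). B and plasma cell markers were higher: of 15 members 11 rose, 0 fell and 4 did not pass, against 12 and 0 over the list alone. Pax5 (1.82) and Mzb1 (2.50) were among the risers (median 1.9, adjusted p = 8.82e-67, 1.44e-04 estimated).

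Antigen presentation by MHC class II, a pathway that B cells share, was higher by camera. Of the 17 members of that list, 6 rose, 0 fell and 11 did not pass, against 8 and 0 over the list alone (median 0.703, camera adjusted p = 6.18e-12, 0.116 with an estimated correlation). H2-DMa (0.65 ± 0.11), H2-Ob (1.18 ± 0.23), Cd74 (1.03 ± 0.19) and H2-Aa (0.88 ± 0.17) led it, with its transactivator Ciita (0.86 ± 0.20). Amino acid and endoplasmic reticulum stress genes were modestly higher: of 24 members 3 rose, 1 fell and 20 did not pass, against 13 and 1 over the list alone (median 0.208, adjusted p = 3.02e-10, 0.0266 estimated). Phgdh (0.78), Trib3 (0.61) and Herpud1 (0.35) rose and Ddit3 (−0.49) fell. Immediate early genes were lower (median −0.151, adjusted p = 1.93e-04, 0.47 estimated), Fos (−0.65), Fosb (−1.10) and Dusp1 (−0.55) falling while Egr3 (2.17) rose. The median was −0.0797 without KO replicate 2 and −0.0702 without WT replicate 1. Collagen and matrix genes were lower too (median −0.54, adjusted p = 1.40e-10, 0.47 estimated), where 1 of 28 members fell, and so were fibroblast markers (median −0.56, adjusted p = 1.31e-04, 0.483 estimated, median −0.367 without KO replicate 3). Ribosomal protein genes, a sign of RNA quality, were higher (median 0.176, adjusted p = 1.40e-10, 0.557 estimated).

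Among other genes, the collagenase gene Mmp13 (−0.86 ± 0.15), the neuropeptide gene Npy (−1 ± 0.137), the signalling regulator Rgs1 (−0.87 ± 0.10) and the interferon-inducible Ifi203 (−1.04 ± 0.15) fell in BMDM. The eosinophil-attracting chemokine gene Ccl24 (2.00 ± 0.33), the growth factor gene Csf1 (1.73 ± 0.15) and the clotting factor gene F13a1 (1.56 ± 0.20) rose. The receptor and ligand genes Cd244a (1.04 ± 0.20), Tnfsf4 (1.49 ± 0.33) and Il5ra (2.61 ± 0.56) rose, while Siglec1 (−0.72 ± 0.10), Lgals9 (−0.43 ± 0.08) and Tlr3 (−0.34 ± 0.07) fell. These genes had edgeR adjusted p from 1.06e-04 to 0.0316. At unadjusted p under 0.05 there were 1825 genes. Groups did not overlap in 14.9% of genes against 10% by chance. The number of calls was 97 without KO replicate 1, 113 without KO replicate 2 and 120 without WT replicate 1, against 203 with all libraries. Without KO replicate 3, which carried M1-type transcripts, 148 genes were higher and 114 lower.

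In M1 macrophages of the knockout, 12 of 37 inflammatory and 6 of 26 co-stimulation genes rose, while 4 of 22 lipid-handling and 11 of 39 lysosomal genes fell (3 KO, 3 WT). The cytokine genes Il6 (2.51 ± 0.51) and Il12b (1.41 ± 0.26) rose. The NF-kB members Rel (0.55 ± 0.09), Nfkb1 (0.35 ± 0.06) and Tnip3 (0.62 ± 0.10) and the activation gene Cd83 (0.87 ± 0.10) rose (edgeR adjusted p from 6.87e-05 to 0.011). Il6 (ENSMUSG00000025746, chromosome 5, 30013114 to 30019981) stood at 83.7 ± 7.35 against 14.7 ± 2.86 CPM. The lipase gene Mgll (−1.93 ± 0.21) and the fatty acid carriers Fabp5 (−1.27 ± 0.10) and Fabp4 (−1.08 ± 0.22) fell. Their regulator Pparg (−0.72 ± 0.08) and Lpl (−0.69 ± 0.10) fell too (edgeR adjusted p from 1.29e-06 to 0.00868). Mgll (ENSMUSG00000033174, chromosome 6, 88724412 to 88828360) fell by 3.82-fold. In all, 770 genes were higher and 613 lower of 17851, with 37 immunoglobulin genes among the higher.

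Large rises also lay in genes of the Ifi200 family in 1 cluster on chromosome 1, Ifi213 (4.73 ± 0.61), Ifi206 (4.72 ± 0.70), Ifi208 (2.79 ± 0.50) and Ifi205 (2.23 ± 0.61). Ifi209 (1.54 ± 0.39) and Mndal (1.36 ± 0.14) of the cluster rose too (edgeR adjusted p from 4.56e-05 to 0.0477). These paralogs share long sequences, so the split of reads between them is uncertain. The adhesion gene Igsf9 (3.07 ± 0.28) of the same region rose too. Of the 51 members of the interferon I antiviral list, 4 rose, 0 fell and 47 did not pass, against 5 and 0 over the list alone (median 0.146, camera adjusted p = 0.00124, 0.926 with an estimated correlation). The risers were Dhx58 (0.36 ± 0.09), Samd9l (0.26 ± 0.07) and, of the cluster, Ifi209 and Mndal. Of the 48 members of the interferon gamma response list, 1 rose, 1 fell and 46 did not pass, the same as over the list alone (median 0.25, adjusted p = 0.115). F830016B08Rik (1.43) was higher and Irf8 (−0.44) lower. That list passed without M1 KO replicate 2 (median 0.294, adjusted p = 0.0358) or WT replicate 1 (0.300, 0.0378).

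Co-stimulation and checkpoint genes were higher: of 26 members 6 rose, 0 fell and 20 did not pass, against 8 and 0 over the list alone (median 0.414, camera adjusted p = 8.09e-09, 0.00143 with an estimated correlation). Among them were Cd80 (0.88 ± 0.09), Icosl (1.13 ± 0.15), Ctla4 (3.19 ± 0.43) and Cd244a (1.55 ± 0.20). Dendritic cell maturation genes were higher too: of 20 members 9 rose, 0 fell and 11 did not pass, against 10 and 0 over the list alone (median 0.625, adjusted p = 1.45e-15, 0.00737 estimated). They were led by Il4i1 (1.66 ± 0.17) and Ccr7 (1.93 ± 0.22), the latter a lymph node homing receptor. Of the 37 NF-kB targets and inflammatory cytokines, 12 rose, 0 fell and 25 did not pass, against 14 and 0 over the list alone (median 0.309, adjusted p = 3.12e-09, 0.202 estimated, median 0.185 without WT replicate 2). Of the 26 glycolysis and hypoxia genes, 10 rose, 0 fell and 16 did not pass, against 14 and 0 over the list alone (median 0.271, adjusted p = 2.17e-09, 0.194 estimated). Bnip3 (1.03) and Pdk1 (0.54) were among the risers. Classical activation markers were higher (median 0.381, adjusted p = 0.00313, 0.851 estimated, median 0.228 without KO replicate 3), 6 of 25 rising, with Gpr18 (0.86). So were interferons and their receptors (median 0.152, adjusted p = 0.00529, 0.323 estimated), with Tmem173 (0.47) and Jak2 (0.39).

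Lysosome and phagocytosis genes were lower in M1 KO: of 39 members 2 rose, 11 fell and 26 did not pass, against 3 and 15 over the list alone (median −0.212, camera adjusted p = 2.51e-06, 0.362 with an estimated correlation). Cd68 (−0.92), Gaa (−0.66) and Trem2 (−0.66) fell and Fcgr2b (1.12) rose. Cholesterol efflux and lipid handling genes were lower (median −0.215, adjusted p = 5.93e-05, 0.0898 estimated, 4 of 22 falling). Oxidative phosphorylation genes were lower by little (median −0.0884, adjusted p = 0.00178, 0.851 estimated, 2 of 35 falling). The thyroid hormone deiodinase gene Dio2 (−1.62 ± 0.27), Npy (−1.56 ± 0.14), Tmem178 (−1.52 ± 0.15), Clmp (−1.50 ± 0.18), Bsn (−1.29 ± 0.20) and F10 (−1.27 ± 0.25) were the other largest falls (edgeR adjusted p from 8.01e-06 to 0.00799). Complement and coagulation as a list did not pass (median −0.221, adjusted p = 0.408). The chemokine genes Ccl3 (1.05), Ccl4 (0.97) and Ccl22 (1.34) and Cd14 (1.65) rose and Egr1 (−0.92) and Egr2 (−1.13) fell (edgeR adjusted p from 1.20e-04 to 0.0158).

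In M1 as in BMDM, B and plasma cell markers were higher (median 1.82, camera adjusted p = 8.67e-23, 0.0104 with an estimated correlation, 11 of 15 rising). At unadjusted p under 0.05 there were 3748 genes. Groups did not overlap in 27.0% of genes against 10% by chance. Calls numbered 907 without KO replicate 1, 836 without WT replicate 2 and 873 without WT replicate 3, against 1383.

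In M2 macrophages of the knockout, B-lineage genes were higher and few genes were lower (2 KO, 3 WT). Ms4a1 (3.17 ± 0.28), Igha (2.88 ± 0.21), Ighm (2.71 ± 0.27), Jchain (2.67 ± 0.16), Igkc (2.50 ± 0.38) and Cd79b (2.02 ± 0.24) rose (edgeR adjusted p from 7.37e-08 to 0.0136). Ms4a1, the CD20 gene (ENSMUSG00000024673, chromosome 19, 11249675 to 11266241), stood at 11.8 ± 0.683 against 1.31 ± 0.419 CPM. Ccl24 (1.52 ± 0.31) and the integrin gene Itgb2l (1.15 ± 0.23) rose too. Npy and Ifi203 fell again, at −0.94 ± 0.16 and −0.94 ± 0.17. They were joined by Stra6l (−0.60 ± 0.10), Ghitm (−0.57 ± 0.07), Ncoa4 (−0.57 ± 0.11), Arhgap25 (−0.54 ± 0.12) and Pstpip1 (−0.49 ± 0.10) (edgeR adjusted p from 2.49e-04 to 0.0448). Ghitm, a mitochondrial membrane gene, and Ncoa4, the ferritin autophagy receptor gene, lie on chromosome 14 near Prkcd.

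There were 83 higher and 18 lower genes of 17851, 29 of the higher being immunoglobulin genes. B and plasma cell markers were higher: of 15 members 10 rose, 0 fell and 5 did not pass, against 12 and 0 over the list alone (median 2.48, camera adjusted p = 1.55e-76, 1.08e-04 with an estimated correlation). MHC class II genes were higher: of 17 members 3 rose, 0 fell and 14 did not pass, against 8 and 0 over the list alone (median 0.487, adjusted p = 1.10e-07, 0.306 estimated). H2-Ob (1.25), H2-DMb2 (1.05) and Cd74 (1.07) rose. Neutrophil markers were higher as a group (median 0.904, adjusted p = 1.33e-11, 0.105 estimated, median 0.491 without KO replicate 2), with 0 of 18 called and 13 higher over the list alone. So were mast cell, basophil and eosinophil markers (median 1.05, adjusted p = 1.15e-08, 0.0379 estimated), with 0 of 17 called and 8 over the list alone. Adipocyte markers were lower as a group (median −2.17, adjusted p = 5.16e-10, 0.306 estimated, 0 of 16 called). Alternative activation genes, the IL-4 programme, did not separate the genotypes (median 0.103, adjusted p = 0.218), though Pparg (−0.39 ± 0.08) fell.

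Of the 51 members of the interferon I antiviral list in M2, 0 rose, 0 fell and 51 did not pass, the same as over the list alone (median −0.179, camera adjusted p = 0.0236, 0.789 with an estimated correlation). The interferon gamma response list did not pass (median −0.203, adjusted p = 0.18). Both lists turned on WT replicate 1, without which the medians were 0.0947 (adjusted p = 0.0759) and 0.236 (0.00684). The antiviral call also ended without KO replicate 2 (median −0.189, adjusted p = 0.0954) or KO replicate 3 (−0.195, 0.0739). The interferon gamma list passed as lower without WT replicate 2 (−0.314, 0.00134) or WT replicate 3 (−0.323, 0.0026). Calls numbered 40 without KO replicate 2, 61 without WT replicate 1 and 49 without WT replicate 2, against 101, with 1905 genes at unadjusted p under 0.05.

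In unstimulated dendritic cells of the knockout, 8 of 14 B-lineage markers and single granule protease genes rose, while 2 of 26 chemokine and 3 of 20 antioxidant genes fell (3 KO, 3 WT). The azurophil granule protease gene Prtn3 (2.28 ± 0.35), the basophil protease gene Mcpt8 (2.34 ± 0.51), F13a1 (2.46 ± 0.41) and the lectin gene Clec10a (1.61 ± 0.31) rose. So did Igha (2.73 ± 0.39), Jchain (2.26 ± 0.29), Igkc (1.88 ± 0.30) and Ms4a1 (1.54 ± 0.26) (edgeR adjusted p from 0.00767 to 0.0472). Ccl22 (−1.28 ± 0.20) and Cxcl3 (−3.58 ± 0.45), chemoattractants for T cells and neutrophils, fell. So did the cystine carrier Slc7a11 (−1.56 ± 0.31) and the quinone reductase Nqo1 (−2.52 ± 0.40) (edgeR adjusted p from 0.00474 to 0.0458). Nqo1 (ENSMUSG00000003849, chromosome 8, 107388225 to 107403206) measured 1.34 ± 0.621 against 7.73 ± 4.15 CPM. Ifi203 rose here, at 2.02 ± 0.14 (adjusted p = 3.53e-05), whereas it fell in BMDM and M2, and its reads are shared with paralogs.

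In DC, 125 genes were higher and 126 lower of 17437. Among the higher were 26 immunoglobulin genes, and 2863 genes had unadjusted p under 0.05. Genes of NRF2 and oxidative stress were lower: of 20 members 0 rose, 3 fell and 17 did not pass, against 0 and 12 over the list alone (median −0.392, camera adjusted p = 1.49e-09, 0.423 with an estimated correlation). Plasmacytoid dendritic cell markers were lower: of 16 members 0 rose, 3 fell and 13 did not pass, against 1 and 6 over the list alone (median −0.318, adjusted p = 5.05e-06, 0.0693 estimated). Siglech (−0.70), Spib (−0.44) and Atp1b1 (−0.41) fell. Chemokines were lower (median −0.329, adjusted p = 0.00512, 0.72 estimated), 2 of 26 falling, and so were dendritic cell maturation genes (median −0.539, adjusted p = 1.38e-07, 0.563 estimated), 1 of 20 falling. The chemokine call ended without WT replicate 2 (median −0.0856, adjusted p = 0.13), and its median was −0.211 without KO replicate 1. For maturation genes it was −0.286 without KO replicate 2 and −0.852 without KO replicate 3. Glycolysis and hypoxia genes were higher (median 0.569, adjusted p = 3.62e-14, 0.482 estimated). Of these 26, Pfkp (0.71) was called, and 22 were higher over the list alone. B and plasma cell markers were higher (median 1.72, adjusted p = 8.74e-22, 0.0409 estimated, 8 of 14 rising).

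Of the 48 members of the interferon gamma response list in DC, 1 rose, 0 fell and 47 did not pass, against 2 and 0 over the list alone (median 0.573, camera adjusted p = 2.16e-04, 0.85 with an estimated correlation). Il12rb1 (1.80 ± 0.35) was the riser. The interferon I antiviral list did not pass: of 51 members 0 rose, 1 fell and 50 did not pass, against 2 and 1 over the list alone (median −0.0863, adjusted p = 0.354). Mx1 (−0.69 ± 0.15) fell (edgeR adjusted p = 0.0487). Without DC KO replicate 3 the interferon gamma median was −0.130 (adjusted p = 0.978) and the antiviral list passed as lower (−0.327, 6.6e-07). Without WT replicate 3 they were 0.364 (0.0557) and −0.155 (0.0197), and the antiviral median turned positive without KO replicate 1 (0.0501) or WT replicate 2 (0.0791).

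Other falls in DC were Tmem26 (−2.10 ± 0.35), Pigr (−1.98 ± 0.41), Dnah2 (−1.73 ± 0.32), Itgb8 (−1.71 ± 0.32), Rnf128 (−1.60 ± 0.34) and Mtss1l (−1.57 ± 0.23) (edgeR adjusted p from 0.00892 to 0.0492). Ribosomal protein genes, a sign of RNA quality, were higher (median 0.261, camera adjusted p = 2.60e-14, 0.563 with an estimated correlation, median 0.174 without KO replicate 1). Each DC library moved the number of calls, from 251 with all to 44 without KO replicate 1, 73 without KO replicate 2, 929 without KO replicate 3, 52 without WT replicate 1, 52 without WT replicate 2 and 144 without WT replicate 3. Of all genes, 21.1% did not overlap between the groups against 10% by chance.

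In stimulated dendritic cells of the knockout, single interferon gamma-responsive and cytotoxic lymphocyte genes were higher and single lysosomal and integrin genes lower (3 KO, 3 WT). Gbp10 (2.85 ± 0.61), Upp1 (2.19 ± 0.28), Il12rb1 (1.34 ± 0.31) and F830016B08Rik (2.91 ± 0.67), all interferon gamma-responsive, rose. The cytotoxic lymphocyte genes Prf1 (4.99 ± 0.96), Tbx21 (2.01 ± 0.45), Nkg7 (1.99 ± 0.48) and Klrk1 (1.40 ± 0.17) rose with them (edgeR adjusted p from 0.00183 to 0.0324). Prf1, the perforin gene (ENSMUSG00000037202, chromosome 10, 61297833 to 61304680), measured 0.872 ± 0.603 against 0.0251 ± 0.00903 CPM. The integrin genes Itgae (−2.03 ± 0.28) and Itgb8 (−1.52 ± 0.30), the scavenger receptor gene Marco (−1.70 ± 0.42) and the acid phosphatase gene Acp5 (−1.29 ± 0.24) fell (edgeR adjusted p from 0.00391 to 0.0463). In all, 456 genes were higher and 629 lower of 17437, and 48 of the higher were immunoglobulin genes.

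Of the 48 members of the interferon gamma response list in DCstim, 4 rose, 0 fell and 44 did not pass, against 11 and 0 over the list alone (median 0.91, camera adjusted p = 7.05e-11, 0.651 with an estimated correlation, and median 0.606 without KO replicate 3). The interferon I antiviral list did not pass: of 51 members 2 rose, 0 fell and 49 did not pass, the same as over the list alone (median 0.109, adjusted p = 0.0956). Ifi209 (1.14) of the chromosome 1 cluster and Ifi27l2a (1.25) were its risers. It passed without KO replicate 1 (median 0.178, adjusted p = 0.00742) or WT replicate 1 (0.144, 0.0479), and its median was −0.0169 without KO replicate 3. The interferon receptor genes Ifnar1 (−0.28 ± 0.07) and Ifnar2 (−0.33 ± 0.08) and Tlr7 (−0.71 ± 0.13) fell. Ifi213 (4.37 ± 0.69) and Ifi206 (2.37 ± 0.49) of that cluster rose again (edgeR adjusted p from 0.00915 to 0.0442), with the same doubt over shared reads.

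CD8 T and NK cytotoxic markers were higher in DCstim: of 14 members 4 rose, 0 fell and 10 did not pass, against 6 and 0 over the list alone (median 1.38, camera adjusted p = 7.21e-04, 0.641 with an estimated correlation). T cell markers were higher (median 1.12, adjusted p = 0.00131, 0.468 estimated), Thy1 (1.52) rising and Cd4 (−1.21) falling. Co-stimulation and checkpoint genes were higher by camera (median 0.321, adjusted p = 0.0486, 0.651 estimated), Cd80 (0.84) and Tnfsf4 (0.87) rising and Havcr2 (−0.98) and Sirpa (−0.52) falling. Of the 26 glycolysis and hypoxia genes, 5 rose, 0 fell and 21 did not pass, against 14 and 0 over the list alone (median 0.567, adjusted p = 5.47e-12, 0.596 estimated). Pfkp (0.93), Hk1 (0.55), Ndrg1 (1.05) and Aldoa (0.63) rose. Of the 39 lysosome and phagocytosis genes, 1 rose, 5 fell and 33 did not pass, the same as over the list alone (median −0.249, adjusted p = 1.04e-04, 0.651 estimated). Hexa (−0.61), Npc1 (−0.70) and Itgb2 (−0.44) fell. Without KO replicate 3 the medians of the cytotoxic, T cell and lysosome lists were 0.871, 0.729 and −0.501, and the last was −0.163 without KO replicate 1. The co-stimulation call ended without KO replicate 3 (0.253, adjusted p = 0.292), WT replicate 1 (0.371, 0.0764) or WT replicate 3 (0.244, 0.137). Plasmacytoid markers were lower (median −0.238, adjusted p = 2.77e-04, 0.218 estimated, Siglech (−1.09)). B and plasma cell markers were higher (median 1.62, adjusted p = 1.71e-16, 0.109 estimated), 9 of 14 rising.

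Further falls in DCstim were Slc1a2 (−2.22 ± 0.36), Olfml3 (−2.11 ± 0.37), Ptprm (−1.52 ± 0.25), Fam234b (−1.33 ± 0.13) and Lox (−1.22 ± 0.13). Gimap4 (2.51 ± 0.44), a lymphocyte GTPase gene, and the cytokine-signal inhibitor Cish (1.81 ± 0.33) rose (edgeR adjusted p from 6.57e-04 to 0.0112 over the first 5, Gimap4 and Cish). Ribosomal protein genes were higher (median 0.116, camera adjusted p = 0.00627, 0.829 with an estimated correlation). At unadjusted p under 0.05 there were 3811 genes. Groups did not overlap in 27.9% of genes against 10% by chance. Calls numbered 502 without KO replicate 2, 321 without WT replicate 1 and 241 without WT replicate 2, against 1085.

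In immature myeloid cells of the knockout, 10 of 13 B-lineage markers and a few interferon-stimulated genes rose, while 3 of 16 mast cell, basophil and eosinophil markers fell (3 KO, 3 WT). Igha (2.51 ± 0.23), Jchain (2.39 ± 0.24), Igkc (2.28 ± 0.22), Cd79a (1.91 ± 0.14), Cd79b (1.87 ± 0.22) and Ighm (1.71 ± 0.10) rose (edgeR adjusted p from 6.45e-04 to 0.0144). So did Sh2d1b1 (2.23 ± 0.24) and Olfml2b (1.67 ± 0.14), both on chromosome 1. The interferon-stimulated genes Oasl1 (0.82 ± 0.13), Isg20 (0.59 ± 0.10), Cxcl10 (0.91 ± 0.10) and Igtp (0.60 ± 0.08) rose (edgeR adjusted p from 0.0109 to 0.0467). Cxcl10 (ENSMUSG00000034855, chromosome 5, 92346638 to 92348889) stood at 16.9 ± 1.61 against 8.95 ± 0.337 CPM. Alox15 (−1.91 ± 0.30), Gata2 (−0.94 ± 0.09), Cpa3 (−0.77 ± 0.12) and Ccr3 (−1.11 ± 0.19), genes of mast cells and eosinophils, fell. So did Slc36a2 (−1.97 ± 0.18), Fstl1 (−1.52 ± 0.17), Lama5 (−1.11 ± 0.12), Cd302 (−1.05 ± 0.10), Il1a (−0.91 ± 0.10) and Ly75 (−0.83 ± 0.10) (edgeR adjusted p from 0.00601 to 0.0498).

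Of the 51 members of the interferon I antiviral list in iMC, 2 rose, 0 fell and 49 did not pass, against 16 and 0 over the list alone (median 0.464, camera adjusted p = 1.46e-25, 0.463 with an estimated correlation). In the interferon gamma response list, of 48 members 2 rose, 0 fell and 46 did not pass, against 8 and 2 over the list alone (median 0.229, 3.42e-04, and 0.567 estimated). The interferon gamma call ended without KO replicate 3 (median 0.109, adjusted p = 0.16). Mast cell, basophil and eosinophil markers were lower: of 16 members 0 rose, 3 fell and 13 did not pass, against 2 and 5 over the list alone (median −0.291, adjusted p = 3.27e-04, 0.463 estimated). Lysosome and phagocytosis genes were lower (median −0.28, adjusted p = 2.95e-08, 0.567 estimated, 2 of 38 falling, Gaa (−0.39) and Npc1 (−0.46)). The mast cell call ended without KO replicate 3 (median −0.188, adjusted p = 0.16), and its median was −0.176 without KO replicate 2 and −0.191 without WT replicate 2. The lysosome median was −0.128 without KO replicate 2 and −0.452 without KO replicate 3. Stress-response genes were higher (median 0.14, adjusted p = 3.42e-04, 0.463 estimated). Ribosomal protein genes were higher (median 0.122, 4.32e-04, 0.737 estimated), with medians of 0.0804 without KO replicate 2 and 0.0759 without WT replicate 2. B and plasma cell markers were higher: of 13 members 10 rose, 0 fell and 3 did not pass, against 12 and 1 over the list alone (median 1.91, adjusted p = 7.41e-62, 0.0182 estimated).

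The iMC comparison had 76 higher and 47 lower genes of 16186, 15 of the higher being immunoglobulin genes. At unadjusted p under 0.05 there were 2295, and groups did not overlap in 20.8% of genes against 10% by chance. Every library moved the number of calls: 22 without KO replicate 1, 70 without KO replicate 2, 1942 without KO replicate 3, 29 without WT replicate 1, 4 without WT replicate 2 and 17 without WT replicate 3.

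In tumours no gene passed edgeR's quasi-likelihood test (5 KO, 6 WT, 17012 genes, smallest adjusted p 0.335). There were 1255 genes at unadjusted p under 0.05, and DESeq2's Wald test called 36 higher and 11 lower. Simulated changes of log2 1 in this design were called for 76.1% of genes. The values of interferon-responsive genes lay above 0, Cxcl11 (1.58 ± 0.35), Ifi27l2a (1.04 ± 0.27), Zbp1 (0.62 ± 0.20) and Acod1 (0.89 ± 0.54) with edgeR adjusted p from 0.516 to 0.716. Cxcl11, a T cell chemoattractant gene (ENSMUSG00000060183, chromosome 5, 92359544 to 92365485), stood at 14.4 ± 6.66 against 4.83 ± 1.69 CPM.

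Several immune gene groups were higher in KO tumours by camera, each call being lost with an estimated correlation. Of the 51 members of the interferon I antiviral list, 0 rose, 0 fell and 51 did not pass, against 12 and 0 over the list alone (median 0.399, camera adjusted p = 9.23e-31, 0.228 estimated). In the interferon gamma response list, of 48 members 0 rose, 0 fell and 48 did not pass, against 1 and 0 over the list alone (median 0.504, 3.87e-20, 0.228 estimated). MHC class I processing was higher (median 0.323, adjusted p = 5.78e-14, 0.228 estimated), 6 members passing over the list alone. The near-identical genes H2-Q7 (0.91 ± 0.19) and H2-Q6 (0.86 ± 0.19) belong to it. MHC class II was higher as well (median 0.536, adjusted p = 2.96e-06, 0.324 estimated, H2-Eb1 (1.04 ± 0.48)). T cell markers were higher (median 0.907, adjusted p = 2.80e-15, 0.228 estimated), 9 of 17 over the list alone. CD8 T and NK cytotoxic markers were higher (median 0.77, adjusted p = 3.61e-08, 0.228 estimated, Klrk1 (0.98 ± 0.31) and Gzmb (0.77 ± 0.31)). Monocyte and macrophage markers were higher (median 0.478, adjusted p = 4.32e-07, 0.344 estimated, Ly6c2 (0.98 ± 0.26) and Lyz2 (0.78 ± 0.26)). So were co-stimulation and checkpoint genes (median 0.327, adjusted p = 8.02e-09, 0.228 estimated, Cd86 (0.89 ± 0.23) and Cd274 (0.77 ± 0.34)). Cell cycle genes were higher by little (median 0.127, adjusted p = 3.61e-08, 0.228 estimated). The class II median was 0.279 without KO7963, and the monocyte and macrophage median was 0.245 without KO7964. With the number of digits of the tumour's number in the fit, which was 4 in 4 of 5 KO and 2 of 6 WT tumours, the interferon gamma median was 0.266, the cytotoxic 0.487 and the monocyte and macrophage 0.295. Ribosomal protein genes, a sign of RNA quality, were higher too (median 0.179, adjusted p = 8.18e-04, 0.703 estimated, 0.237 with the digits). That call ended without WT7869 (0.101, 0.108) or KO7870 (0.0494, 0.396), and the median was 0.114 without WT162.

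Stromal and blood groups were lower in KO tumours or flat. Skeletal muscle markers were lower by camera (median −1.86, camera adjusted p = 2.24e-09, 0.344 with an estimated correlation, Myh1 (−2.27 ± 1.10)). Erythroid and platelet markers were lower (median −0.852, adjusted p = 1.78e-04, 0.228 estimated, Hba-a2 (−2.18 ± 0.85)). Epithelial markers (median −0.214, adjusted p = 5.46e-04, 0.53 estimated) and endothelial markers (median −0.261, adjusted p = 0.0122, 0.666 estimated) were lower by less. Collagen and matrix genes were lower too (median −0.139, adjusted p = 0.00572, 0.693 estimated, Col1a1 (−0.73 ± 0.86)). Fibroblast markers (median −0.0812, adjusted p = 0.107), adipocyte markers (median 0.0708, adjusted p = 0.515) and neutrophil markers (median −0.00812, adjusted p = 0.444) did not pass. Haematopoietic progenitor markers (median −0.032, adjusted p = 0.984) and suppressive myeloid genes (median 0.0537, adjusted p = 0.501) did not pass either. Markers of B and plasma cells, at least 1.62 in median in each culture, had median 0.51, adjusted p = 0.0122, 0.482 estimated. The B-cell call ended without WT121 (0.526, 0.085) or KO7963 (0.339, 0.0735), and the epithelial call without WT166 (−0.026, 0.24). The endothelial call ended without KO120 (−0.249, 0.0724), WT121 (−0.243, 0.0506), WT162 (−0.0893, 0.25), KO7870 (−0.174, 0.0739) or KO7963 (−0.159, 0.205), and its median was −0.446 without KO7964. The matrix call ended without WT162 (−0.0148, 0.406) or KO7963 (−0.0913, 0.139), with medians of −0.236 without WT7807, −0.0758 without KO7870 and −0.499 without KO7964. Skeletal muscle markers were at −3.09 without KO7964. Fibroblast markers passed as lower without WT166 (−0.184, 0.0497), WT7807 (−0.159, 0.0457) or KO7964 (−0.505, 3.22e-06), and neutrophil markers without KO7963 (−0.225, 0.0144) or KO7964 (−0.0626, 0.0129). Suppressive myeloid genes passed without KO120 (0.265, 0.0411) or KO7870 (0.251, 0.0493), and adipocyte markers without KO120 (0.234, 0.0188) or KO7862 (−0.00924, 0.0275). With the digits in the fit the B-cell (0.23, 0.613) and endothelial (−0.194, 0.0959) calls ended, and epithelial and skeletal muscle medians were −0.0891 and −3.0. Tumour WT166 had the lowest depth (23.4 M) and 24.0% of its reads on ribosomal RNA genes. Leaving out any 1 tumour gave 0 calls.

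**Figure D2:**
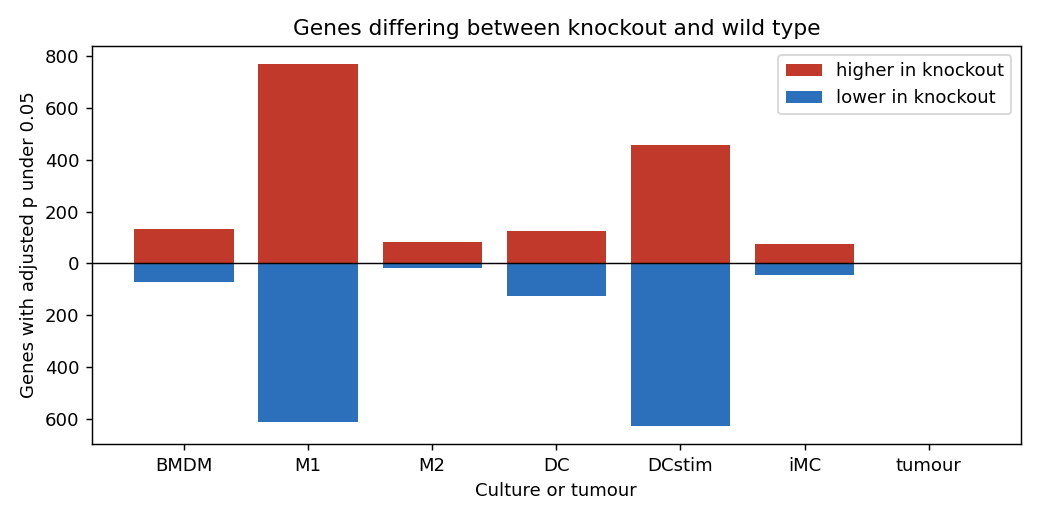
Number of genes (axis) higher and lower in KO than in WT at adjusted p under 0.05 in each kind of sample. M1 has the most calls (770 higher, 613 lower) and tumours have 0.

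**Figure D3:**
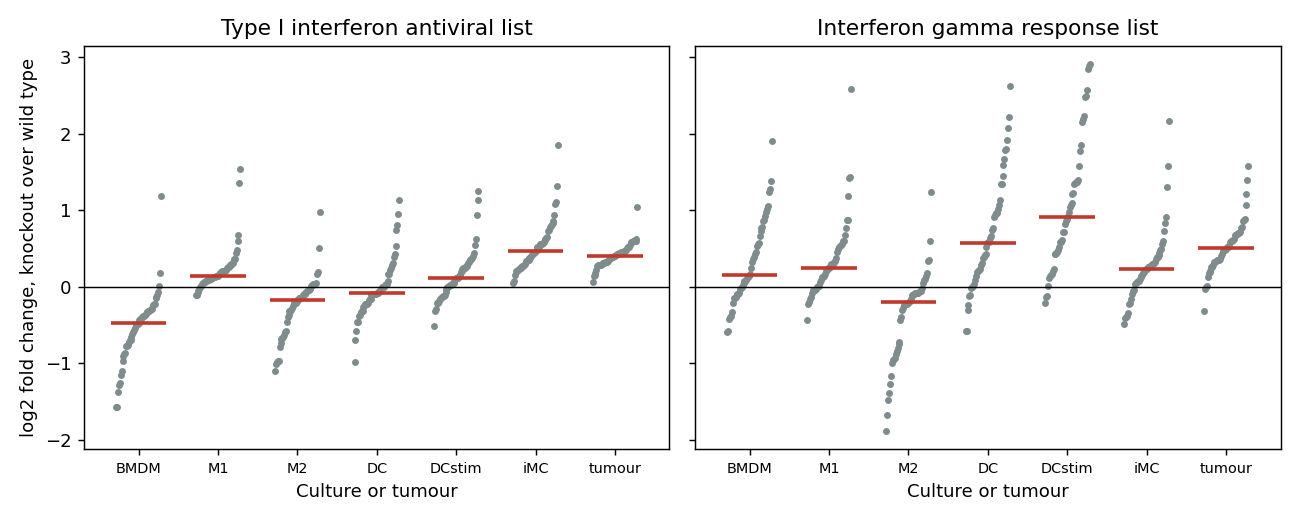
Log2 fold change (KO over WT) of each member of the interferon I antiviral and interferon gamma response lists in the 7 genotype comparisons, with the median as a red line. The antiviral list lies under 0 in BMDM (median −0.48) and over 0 in iMC (0.464) and tumours (0.399).

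Interferon gamma and LPS moved most tested genes in macrophages of each genotype (3 M1, 3 BMDM per genotype). In WT, Coch (8.22 ± 0.81), Nos2 (8.16 ± 1.57), Cxcl9 (7.82 ± 1.33), Acod1 (7.67 ± 1.45) and Clic5 (7.64 ± 0.95) rose most, Nos2 making nitric oxide and Acod1 itaconate. Granulocyte genes Elane (−6.19 ± 0.57), Mpo (−5.81 ± 0.61), Retnlg (−5.41 ± 0.62) and Ngp (−5.30 ± 0.28) fell with Smpd3 (−6.55 ± 0.40) (edgeR adjusted p from 1.70e-09 to 7.43e-04). In KO, Gstt4 (7.89 ± 1.20), Cxcl11 (7.36 ± 1.52), Cxcl10 (7.11 ± 1.19), Nos2 (6.89 ± 1.48) and Ccl5 (6.85 ± 1.40) rose most. The largest falls were Mpo (−7.09 ± 0.63), Elane (−6.64 ± 0.55), Ms4a3 (−6.22 ± 0.53), Ctsg (−6.19 ± 0.51) and Prtn3 (−6.00 ± 0.51) (edgeR adjusted p from 6.70e-08 to 0.00154). The KO baseline holds BMDM KO replicate 3, which carried M1-type transcripts, and without it Cxcl11 was at 9.78, Gstt4 at 9.49 and Nos2 at 9.17. Genes called numbered 4682 higher and 5458 lower in WT and 5015 and 5643 in KO, of 17851. Prkcd itself rose with the stimulus, by 0.65 ± 0.07 in WT and 0.43 ± 0.07 in KO. Nos2 (ENSMUSG00000020826, chromosome 11, 78920787 to 78960254) measured 2140 ± 116 against 7.48 ± 1.18 CPM in WT.

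Interferon I antiviral genes rose in 50 of 51 members in WT (median 2.74, camera adjusted p = 4.81e-30, 0.161 with an estimated correlation). In KO they rose in 51 of 51 (3.53, 1.35e-37, 0.103 estimated). The interferon gamma response list rose in 44 of 48 members in WT (median 4.7, adjusted p = 1.56e-20, 0.162 estimated). In WT, MHC class I processing (median 2.14, adjusted p = 2.75e-23, 0.0478 estimated, 19 of 21 rising) and NF-kB targets (median 3.03, adjusted p = 4.30e-25, 0.0478 estimated, 35 of 37) rose. Classical activation markers (median 5.28, adjusted p = 6.37e-11, 0.205 estimated, 24 of 25) and NRF2 genes (median 1.67, adjusted p = 1.21e-13, 0.0478 estimated, 17 of 20) rose too. Cholesterol biosynthesis (median −2.02, adjusted p = 8.75e-17, 0.162 estimated, 23 of 24 falling) and cell cycle genes (median −2.21, adjusted p = 1.16e-31, 0.0921 estimated, 35 of 37) fell. Ribosomal protein genes fell in 30 of 30 (median −1.36, adjusted p = 1.40e-22, 0.162 estimated).

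The M1 response was higher in KO for 212 genes and lower for 176 (2572 at unadjusted p under 0.05, 3 libraries per group). The difference (KO response less WT response) was positive for Igsf9 (2.18 ± 0.38), Synpo2 (1.90 ± 0.44), Lipg (1.80 ± 0.31) and Sema7a (1.75 ± 0.37). It was negative for Dio2 (−1.67 ± 0.37), Htra4 (−1.66 ± 0.35), Clmp (−1.60 ± 0.26), F13a1 (−1.57 ± 0.30) and Mgll (−1.50 ± 0.28) (edgeR adjusted p from 0.00575 to 0.0408). A positive difference is a larger rise or a smaller fall with the stimulus, and a negative one the reverse. For these genes the sign alone does not tell which. Antiviral genes gained more from stimulation in KO, where they started lower: of 51 members 14 rose, 0 fell and 37 did not pass, against 34 and 0 over the list alone (median 0.654, camera adjusted p = 2.17e-32, 0.307 with an estimated correlation). Dhx58 (1.13 ± 0.13), Mndal (1.70 ± 0.20), Samd9l (0.64 ± 0.10) and Stat2 (0.91 ± 0.15) were among them. Co-stimulation (median 0.374, adjusted p = 1.42e-04, 0.0315 estimated) and dendritic cell maturation genes (median 0.515, adjusted p = 1.37e-09, 0.0486 estimated) had positive differences too. Calls of the difference numbered 248 without BMDM KO replicate 1, 258 without BMDM WT replicate 1, 239 without M1 KO replicate 1, 243 without M1 WT replicate 2 and 243 without M1 WT replicate 3, against 388.

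IL-4 raised the alternative activation programme in both genotypes (3 M2 and 3 BMDM in WT, 2 and 3 in KO). In WT, Retnla (7.96 ± 0.91), Il31ra (7.25 ± 0.35), Kcnd3 (6.87 ± 0.56), Scn3a (6.82 ± 0.39) and Pdcd1lg2 (6.60 ± 0.30) rose most, Retnla encoding a resistin-like protein of alternatively activated macrophages. The largest falls were Retnlg (−4.26 ± 0.57), Pcp4l1 (−3.82 ± 0.18), Gpr162 (−3.21 ± 0.17), Ifitm3 (−3.06 ± 0.19) and Ms4a6b (−2.79 ± 0.16) (edgeR adjusted p from 1.31e-10 to 8.71e-05). In KO, Rnase2a (8.29 ± 0.67), Scn3a (8.19 ± 0.41), Retnla (8.02 ± 0.92), Cldn11 (7.62 ± 0.64) and Kcnd3 (7.45 ± 0.59) rose. Of the falls Plin4 (−5.23 ± 1.37), Cfd (−3.94 ± 1.10), Car3 (−3.74 ± 0.99), Gpr162 (−3.16 ± 0.19) and Pcp4l1 (−3.12 ± 0.20) (edgeR adjusted p from 9.90e-09 to 0.0216), the first 3 were fat-cell genes. Alternative activation markers rose in 25 of 31 members in WT (median 2.12, camera adjusted p = 1.29e-52, 2.71e-05 with an estimated correlation) and 26 in KO (median 2.04, adjusted p = 1.32e-63, 2.15e-05 estimated). Retnla is ENSMUSG00000061100, chromosome 16, 48842551 to 48844461, and Prkcd rose by 1.55 ± 0.07 in WT and 1.18 ± 0.07 in KO.

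IL-4 lowered antiviral genes, 36 of 51 in WT (median −0.977, camera adjusted p = 3.36e-19, 0.316 with an estimated correlation) and 23 in KO (median −0.76, adjusted p = 7.53e-07, 0.605 estimated). Genes called numbered 2726 higher and 2725 lower in WT and 2272 and 2174 in KO. The KO sum was 2761 without M2 KO replicate 3. No gene passed for a different IL-4 response by edgeR's quasi-likelihood test (smallest adjusted p 0.239, 1118 at unadjusted p under 0.05). DESeq2 called 47 higher and 12 lower, and 1 gene passed by edgeR without M2 KO replicate 3. Recovery of simulated differences (68.7% at log2 1) does not exclude real ones. As groups, antiviral genes (median 0.357, adjusted p = 1.04e-17, 0.484 estimated) and collagen and matrix genes (median 1.35, adjusted p = 7.27e-27, 0.143 estimated) were higher in the KO response, with 7 and 18 members higher over the list alone. Fibroblast markers moved with the latter (median 0.852, adjusted p = 2.12e-12, 0.143 estimated). The antiviral median was 0.585 without M2 WT replicate 1.

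LPS and the antibody to CD40 matured dendritic cells of both genotypes (3 DCstim, 3 DC per genotype). In WT, Sprr2d (9.10 ± 0.39), Dll4 (7.89 ± 0.28), Notum (7.46 ± 0.68), Vnn3 (7.00 ± 0.26) and Shisa3 (6.94 ± 0.33) rose most. The largest falls were Cd209a (−4.99 ± 0.22), Hepacam2 (−4.83 ± 0.30), Cd300lg (−4.68 ± 0.28), Hpgd (−4.42 ± 0.42) and Dcstamp (−4.42 ± 0.47) (edgeR adjusted p from 7.32e-09 to 3.85e-05), Dll4 being a Notch ligand and Cd209a an uptake receptor. In KO, Vgf (6.01 ± 0.48), Cxcl11 (5.92 ± 0.72), Dll4 (5.90 ± 0.26), Il6 (5.81 ± 0.32) and Susd2 (5.53 ± 0.16) rose. There, Cd209a (−5.49 ± 0.23), Cd300lg (−5.02 ± 0.29), Hpgd (−5.02 ± 0.43) and Xcr1 (−4.11 ± 0.51) fell (edgeR adjusted p from 1.59e-09 to 1.04e-04). Called genes numbered 3680 higher and 3398 lower in WT and 4211 and 4223 in KO, of 17437. Dll4 is ENSMUSG00000027314, chromosome 2, 119325784 to 119335962, and Prkcd did not move (−0.01 ± 0.07 in WT and −0.11 ± 0.07 in KO).

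Antiviral genes rose in 50 of 51 members in WT (median 2.17, camera adjusted p = 1.27e-36, 0.213 with an estimated correlation). The interferon gamma list rose in 40 of 48 (median 2.73, adjusted p = 4.73e-16, 0.558 estimated). Dendritic cell maturation genes rose in 18 of 20 in WT (median 1.4, adjusted p = 8.42e-12, 0.387 estimated) and 20 of 20 in KO (median 2.29, adjusted p = 2.26e-18, 0.165 estimated). Classical activation markers rose in 21 of 25 (median 3.02, adjusted p = 3.30e-28, 0.105 estimated) and NF-kB targets in 30 of 37 (median 1.86, adjusted p = 1.27e-36, 0.0605 estimated). Cell cycle genes fell in 35 of 37 (median −0.771, adjusted p = 1.33e-11, 0.626 estimated) and conventional dendritic cell markers in 13 of 18 (median −1.18, adjusted p = 2.61e-08, 0.0708 estimated).

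This response was higher in KO for 8 genes and lower for 28 (2514 at unadjusted p under 0.05). Pdgfa (1.44 ± 0.18), Eno2 (1.25 ± 0.15), Car2 (1.17 ± 0.20), Ccdc6 (0.85 ± 0.14) and Cd80 (0.75 ± 0.12) gained more in KO. Gaining less were Sprr2d (−3.95 ± 0.51), Sirpb1a (−2.42 ± 0.31), Dll4 (−1.99 ± 0.31), Ifi203 (−1.79 ± 0.19) and Fcrl5 (−1.70 ± 0.22) (edgeR adjusted p from 0.008 to 0.0379). As groups, dendritic cell maturation genes (median 0.748, camera adjusted p = 7.18e-12, 0.997 with an estimated correlation) and the interferon gamma list (median 0.285, adjusted p = 0.0167, 0.997 estimated) were higher in the KO response. The antiviral list was higher by less (median 0.171, adjusted p = 0.0324, 0.997 estimated). The interferon gamma median turned without DCstim KO replicate 3 (−0.0648, adjusted p = 0.55). The call also ended without DC KO replicate 1 (0.0999, 0.284), DC KO replicate 2 (0.0644, 0.355) or DC WT replicate 2 (0.224, 0.186), and the median was 0.843 without DC KO replicate 3 and 0.432 without DCstim KO replicate 1. The antiviral call ended without DC KO replicate 1 (0.0454, 0.457), DC KO replicate 2 (0.0523, 0.275), DC WT replicate 2 (0.0187, 0.58), DCstim KO replicate 3 (0.0438, 0.484) or DCstim WT replicate 3 (0.133, 0.139). Its median was 0.474 without DC KO replicate 3 and 0.275 without DC WT replicate 3. Same-numbered DC and DCstim libraries deviated together within each genotype. With the replicate number as a block within genotype the calls numbered 449 (216 higher, 233 lower). Calls of the difference were 369 without DC KO replicate 3, 91 without DCstim KO replicate 3, 63 without DCstim WT replicate 3 and 55 without DCstim KO replicate 1, against 36 with all. Leaving out any other DC or DCstim library gave 9 to 19.

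Genotype calls were shared between cultures more often than by chance. Of 18788 genes, 204 were higher and 164 lower in at least 2 cultures, 87 and 14 in at least 3, and 11 and 1 in all 6. Among the 11 were the B-lineage genes Cd79a, Igha, Igkc, Iglc2, Jchain, Ms4a1, Mzb1, Pax5 and Pou2af1 and the gene model Gm6768, and the 1 was Ncoa4 (ENSMUSG00000056234, chromosome 14, 32159865 to 32179855). BMDM and M2 shared 60 higher genes against 0.614 expected, BMDM and M1 75 against 5.69, and M1 and DCstim 97 higher against 20.5 and 89 lower against 22.5, with 34 higher in M1 and lower in DCstim and 5 the reverse. Over all genes the log2 fold changes correlated at 0.483 between BMDM and M1 and 0.234 between M1 and DCstim, but at −0.214 between BMDM and M2 and −0.22 between M1 and M2. Same-numbered cultures of 1 genotype deviated together in several pairs of groups, so the cultures were not shown to be independent of each other.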

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

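The tests of the B-lineage rise, of the strain variants, of the same-group baseline, of M2 WT replicate 1 alone and of groupings that keep same-numbered libraries together were chosen after the result was seen. The other tests of explanations and the other regroupings were chosen before. B-lineage transcripts were higher in KO in all 6 cultures. The lowest share of positive markers over the cultures was 86.7%, which restates the pattern and tests no explanation of it. If RNA of tumour libraries had entered instead, collagen genes should be raised at least as far, and their median lay under that of B-cell markers in 6 of 6 cultures. Whether living B cells, plasma cells, carried-over marrow RNA or a change of expression gave the rise stays open.

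Transcripts typical of M1 (55 genes) stood at 3.27% of their M1 level in BMDM KO replicate 3 and 2.95% in M2 WT replicate 1. The other BMDM and M2 libraries had 0.443% to 1.79%, kept low by choosing genes at least 50-fold higher in M1. RNA or reads of an M1 culture mixed in at 1 share should give a narrow spread of shares. The ratio of the upper to the lower quartile was at most 1.38 with both genotypes as the baseline and 1.21 with the same group. A weak response of these cultures themselves should give different shares by gene list, but in M2 WT replicate 1 the ratio of the highest to the lowest list was 1.12 with the first baseline and 1.02 with the second (upper ends of resampled intervals 1.37 and 1.54), which argues against it there. In BMDM KO replicate 3 the antiviral list had a share of −0.297% with the first baseline, which left the ratio undefined, and the ratio was 1.16 with the second, chosen after that was seen, so for this library the exclusion hangs on the baseline. The raised level in these 2 libraries bears on the interferon lists of BMDM and M2. It lowers the fold of M1-induced genes in the KO M1 response.

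Genotype calls gathered on chromosomes 1 and 14. Genes called in 2 or more cultures made up 31 of the tested genes (26.1%) at chromosome 1, 169497934 to 174497934, against 2.05% of all, and 14 of 130 (10.8%) within 10 Mb of Prkcd against 1.98% elsewhere (Fisher p = 4.45e-07). Of 1000 random redistributions of the calls over genes 0 had a window as dense (highest 13), but 113 of 1000 circular shifts did, since shifts keep the clustering of the calls. If 1 interferon-inducible cluster explained the chromosome 1 window, most of its calls should be interferon-inducible, but 35.5% were Ifi200 family or M1-induced genes (11 of 31). Stretches of another strain's sequence around the targeted gene and on chromosome 1 would give both groups, and variants were not examined here.

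Regroupings of the libraries served as a further test. With 10 groupings the splits are too few to exclude chance, and the real grouping called the most genes (rank 1) in BMDM (203, highest other 2, and 0 among those that also part all 3 same-numbered pairs), M1 (1383, other 2), DC (251, other 0), DCstim (1085, other 0) and iMC (123, other 12). It was also first for the stimuli, with 10140 against 0 for M1 in WT, 10658 against 0 for M1 in KO, 5451 against 1 for M2 in WT, 7078 against 0 for DCstim in WT and 8434 against 0 for DCstim in KO. For the antiviral list the real median ranked 2 in BMDM (−0.48, highest other 0.553 in size), 2 in M1 (0.146, 0.148), 6 in DC (−0.0863, 0.557), 6 in DCstim (0.109, 0.196) and 1 in iMC (0.464, 0.426). For the interferon gamma list it ranked 9 in BMDM (0.157, 0.548), 1 in M1 (0.25, 0.228), 7 in DC (0.573, 0.887), 1 in DCstim (0.91, 0.66) and 1 in iMC (0.229, 0.204).

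In tumours the real grouping called 0 genes, which each of the 100 groupings reaches (highest 157), so this count says nothing about chance. The antiviral median was reached by 3 of 100 groupings (0.399, highest other 0.466) and the interferon gamma median by 4 of 100 (0.504, highest other 0.623), shares under 0.05 for the 2 lists taken singly in this draw of 100 from 462. Both calls were lost with an estimated correlation (0.228) and by fry (0.203), so the lists stay uncertain. Of the groupings 4 called any gene. The 1 with 157 calls, which points to a structure of the samples, set WT119, WT162, WT7807, WT7869 and KO7964 against the rest, and 1 with 41 calls differed from the real one only by exchanging KO120 for WT166. Both lie near the genotypes, so whether the structure is apart from genotype stays open. The antibody given to each host is not in the labels and was not tested.

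The genotypes differed in response for 388 genes in M1, a count reached by 3 of 50 groupings (highest other 442), which decides nothing, since the 4 others with high counts (240 to 442) kept the M1 libraries by genotype and so carry its difference. The 45 that mixed the M1 genotypes had at most 4, but were drawn without keeping same-numbered BMDM KO and M1 KO libraries together, which deviated together. With same-numbered libraries kept together and as a block, 508 genes differed and the highest other grouping had 2, but 10 groupings are too few to exclude chance. The antiviral list differed in M1 response by 0.654 and in IL-4 response by 0.357, both lost with an estimated correlation (adjusted p = 0.307 and 0.484). For DCstim 36 genes differed, a count reached by 1 of 50 groupings, the real one (highest other 16), but these too were drawn without keeping same-numbered DC and DCstim libraries together, which deviated together. With such pairs kept together and as a block, 449 genes differed and the highest other of 10 groupings, again too few, had 0. The antiviral and interferon gamma lists differed in DCstim response by 0.171 and 0.285, both lost with an estimated correlation (0.997 for each), and the latter turned to −0.0648 without DCstim KO replicate 3.

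Dixon's test was run on 13 measures in the 2 tumour groups, 26 tests in all, of which chance marks 1 in 20, and 5 values stood out. Tumour WT166 had the lowest depth of its group (23.4 M), the highest share on ribosomal RNA genes (24.0%) and the highest share on its top 50 genes (40.0%). Tumour KO7963 had the lowest mean of the antiviral list (5.57 in log2 TPM) and tumour WT121 the lowest mean of macrophage markers (4.65).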

How the results depend on the processing

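Which lists passed depended on the correlation assumed between genes, and the calls of the interferon lists were lost with an estimated correlation. For the antiviral list the adjusted p became 0.189 in BMDM (median −0.48), 0.926 in M1 (0.146), 0.789 in M2 (−0.179), 0.463 in iMC (0.464) and 0.228 in tumours (0.399), and by fry 0.0604, 0.431, 0.759, 0.217 and 0.203. For the interferon gamma list it became 0.85 in DC (0.573), 0.651 in DCstim (0.91), 0.567 in iMC (0.229) and 0.228 in tumours (0.504), and by fry 0.606, 0.226, 0.227 and 0.203. Of 116 calls of other lists over the genotype comparisons, 9 stayed with an estimated correlation and 22 by fry.

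Counts of genes moved with the test. DESeq2's Wald test called 446 in BMDM, 362 in M2, 997 in DC, 1982 in DCstim, 715 in iMC and 47 in tumours, 881, 59 and 654 for the differences in M1, M2 and DCstim response, and 1060 shared between cultures against 368. Length-scaled counts gave 126 in BMDM, 884 in M1, 55 in M2, 124 in DC, 575 in DCstim, 25 in iMC (18 higher, 7 lower), 197, 2 and 6 for the differences, and 171 shared. Prkcd was then called in 3 cultures against 5, and Irf8 in the M1 response of KO (0.355) and Hlf in the M2 response of KO (0.582) turned direction. Without the filter on low counts the DCstim difference had 102 calls (36 higher, 66 lower), iMC 252 (125 higher, 127 lower), and the interferon gamma list passed in M1 (0.249, adjusted p = 0.0456). Fits of only the groups compared gave 116 in BMDM, 113 in DC, 598 in DCstim and 2 for the M2 difference, with the interferon gamma list passing in M1 (0.238, 2.88e-07), the antiviral list passing in DCstim (0.102, 0.00712) and no longer in M2 (−0.181, 0.0693).

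With the replicate number as a block, pairing libraries of equal number, the antiviral list no longer passed in M2 (−0.155, adjusted p = 0.164), and calls numbered 1 for the M2 difference, 15 for the DCstim difference and 31 in iMC (23 higher, 8 lower). With the block within genotype they numbered 3 for the M2 difference and 449 for the DCstim difference. Neither block changed another interferon list call or moved another count by over 1.5 times. Of single genes the first block ended 73 calls and added 15, and of other lists it ended 2 and added 4. DESeq2 size factors, the digits of the tumour number and leaving out ribosomal RNA genes moved no count by over 1.5 times and ended no interferon list call, but with the digits the tumour medians of the interferon gamma list fell from 0.504 to 0.266, of interferons and receptors to 0.0813, of cytotoxic markers to 0.487, of monocyte and macrophage markers to 0.295 and of conventional dendritic cell markers to 0.144, and epithelial markers went from −0.214 to −0.0891 and skeletal muscle from −1.86 to −3.0. DESeq2 size factors ended 11 and added 4 calls of single genes. With the digits of the tumour number 8 of 39 tumour lists no longer passed: classical activation (0.266, adjusted p = 0.481), NF-kB targets (0.103, 0.957), chemokines (0.21, 0.141), lysosome (0.149, 0.0804), complement (0.141, 0.108), glycolysis (−0.0334, 0.222), B and plasma cell (0.23, 0.613) and endothelial markers (−0.194, 0.0959). Oxidative phosphorylation (0.0806, 0.0425) and adipocyte markers (0.129, 0.0109) passed anew, and mast cell, basophil and eosinophil markers went from 0.0995 (0.984) to −0.104 (0.0318).

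Leaving out BMDM KO replicate 3 and M2 WT replicate 1 together turned the interferon gamma list in BMDM to −0.271 (adjusted p = 9.61e-07), the antiviral list in M2 to 0.0909 (0.014) and the interferon gamma list in M2 to 0.231 (7.45e-05). The interferon gamma list then passed in M1 (0.231, 2.72e-04), and 2 genes passed for the M2 difference. BMDM then had 151 higher and 140 lower genes.

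Leaving out 1 library at a time moved the number of calls from 97 to 262 in BMDM, 836 to 1163 in M1, 40 to 120 in M2, 44 to 929 in DC, 241 to 991 in DCstim and 4 to 1942 in iMC, and left 0 in tumours. For responses the range was 9497 to 9603 (M1, WT), 9978 to 10316 (M1, KO), 4557 to 5025 (M2, WT), 2761 to 4376 (M2, KO), 5890 to 6505 (DCstim, WT) and 7359 to 8167 (DCstim, KO), and 239 to 424, 0 to 1 and 9 to 369 for the differences in M1, M2 and DCstim. The antiviral median ran from −0.798 to −0.316 in BMDM, 0.13 to 0.168 in M1, −0.255 to 0.0947 in M2, −0.327 to 0.0791 in DC, −0.0169 to 0.178 in DCstim, 0.374 to 0.59 in iMC and 0.312 to 0.514 in tumours. The interferon gamma median ran from −0.271 to 0.385 in BMDM, 0.162 to 0.3 in M1, −0.323 to 0.236 in M2, −0.13 to 0.837 in DC, 0.606 to 1.05 in DCstim, 0.109 to 0.25 in iMC and 0.366 to 0.604 in tumours. Other turns included NF-kB targets in tumours (−0.0342 without KO7964, 0.326 without KO120). Cell cycle genes turned in M2 (−0.0635 without KO replicate 2, 0.282 without KO replicate 3). The interferon gamma list turned in the DCstim difference (−0.0648 to 0.843). Skeletal muscle markers turned in DC (−0.529 without KO replicate 2, 1.6 without KO replicate 3). Classical activation in BMDM, not called with all, passed at −0.342 without KO replicate 3 and at 0.53 without KO replicate 2. Depth bounds the rarest transcripts seen, and the cause of these movements was not tested.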

Other observations

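The antiviral list was lower in unstimulated KO macrophages (median −0.48) and higher in KO immature cells (0.464) and KO tumours (0.399), but each call was lost with an estimated correlation (adjusted p = 0.189, 0.463 and 0.228). A difference between kinds of sample was not tested, and in BMDM another of the 10 groupings reached 0.553. The interferon gamma list was higher in KO stimulated dendritic cells (0.91), tumours (0.504, and 0.266 with the digits of the tumour number in the fit) and immature cells (0.229), again lost with an estimated correlation (0.651, 0.228 and 0.567), and in immature cells also without KO replicate 3 (0.109, adjusted p = 0.16). In the same samples 2 libraries carried M1-type transcripts, and the direction in M2 and the interferon gamma direction in BMDM turned when both were left out (−0.271 for the latter). The antiviral fall in BMDM might reflect a lower tonic interferon level in the knockout, and interferon beta measured in the culture medium with a receptor-blocking antibody added would test it.

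Genes on the Y chromosome were expressed in all 35 marrow libraries though the labels give female donors: Ddx3y (14.1 to 36.3 TPM), Eif2s3y (44.1 to 95.6), Kdm5d (3.04 to 13.7) and Uty (4.74 to 11.8). In the 11 tumours Eif2s3y was at most 1.82 TPM, and Xist was 3.86 to 11.4 TPM in marrow libraries and 5.62 to 30.4 in tumours. The marrow libraries thus held male and female transcripts together, and genotyping of the donors was not analysed here.

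The gene model Gm6768 (ENSMUSG00000021908, chromosome 12, 119260978 to 119262855) had the lowest p in all 7 genotype comparisons, which was seen only after testing. It measured 65.9 ± 8.47 TPM in BMDM KO against 7.34 ± 0.793 in WT, 33.7 ± 2.1 against 4.33 ± 0.227 in iMC and 3.21 ± 1.59 against 1.25 ± 0.34 in tumours. What the model encodes was not examined here.

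Near Prkcd, Ncoa4 was lower in all 6 cultures (−0.52 in BMDM, −0.84 in DCstim) and Ghitm too, called in 5, while Arhgap22 was lower in 5, called in 3, but called higher in iMC (1.25). As calls gathered near Prkcd, these genes could differ by strain sequence linked to the targeted allele and not by loss of the kinase. Sequence variants called from the raw reads of this region, or KO made by editing in a single strain, would test it.

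The highest values over the 35 marrow libraries were 63.8 TPM for Ifng, 57.2 for Cd8a and 0.436 for Cd3e. The cultures that held them are not given here. Ifng could come from NK or innate lymphoid cells and raise interferon gamma-responsive genes, but the values do not decide it. In KO stimulated dendritic cells the calls of the cytotoxic list (median 1.38) and the interferon gamma list (0.91) were lost with an estimated correlation (adjusted p = 0.641 and 0.651). Of the 10 groupings, too few to exclude chance, the highest other interferon gamma median was 0.66, and flow cytometry of the cultures for NK cells would test it.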
